A study of Mus musculus with 63 samples.

How the data were processed

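RNA was sequenced from the dorsal hippocampus of adolescent mice of the inbred strains C57BL/6J and DBA/2J. Animals of both sexes received ethanol (1.5 g/kg) or saline and were either fear conditioned (FC) or not (noFC), which makes 16 groups of strain, sex, conditioning and drug. Each group held 4 libraries, except fear-conditioned male C57BL/6J mice given saline with 3, for 63 libraries in all. Every title held a number from 310 to 325, shared by the drug and conditioning groups of one strain and sex, and then a letter from A to D. The labels do not say what the number or the letter stands for, and numbers 310 to 317 and 318 to 325 are called the first and second round of titles here. Letters A and B marked saline and C and D ethanol in the first round, and the reverse in the second. Letters A and C marked FC and B and D noFC in both rounds. Drug therefore coincides with the letter within each round, and conditioning in both. Per the labels, tissue was kept in RNAlater, RNA was extracted with Trizol and RNeasy columns, and stranded poly(A) libraries were read from one end on a NextSeq instrument.

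The authors deposited a table of read counts per gene and a table of estimated counts per transcript, with one column per library in each. Per the submitters' processing notes, which give no versions, fastp, HISAT2, featureCounts, Salmon and DESeq2 were used with the mouse build GRCm38. The deposited gene counts were whole numbers for 55401 genes, of which 55141 had an identifier in the GENCODE M21 annotation. The deposited estimated counts covered 117135 transcripts, 46.8% of the values were not whole, and 1.2% of the counts lay on transcripts missing from that annotation. Symbols, gene types and positions were taken from the annotation by identifier, and every library column was matched to its labels by title.

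Gene counts per library ranged from 21027659 to 61631742 (median 26379948). Genes with low counts were removed with filterByExpr (minimum count 10, over the 16 groups), which kept 19974 genes holding 99.95% of the counts and left out 35427. Scaling used TMM factors, which ranged from 0.96 to 1.05. Levels are given as CPM (counts scaled to a common library total) with the standard deviation (SD) between libraries, and log2 values used a prior count of 2. The median standard error (SE) of a log2 difference was 0.042 for strain and sex and 0.059 for ethanol in C57BL/6J. Each library was treated as a separate animal, so the errors cover variation between animals together with counting error.

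Differences between groups were tested with edgeR 4.0.16 (quasi-likelihood fit, one coefficient per group, two-sided). Contrasts were averaged with equal weight over the factors not compared. P-values were adjusted by Benjamini and Hochberg over the 19974 genes of a contrast, and a gene was called at an adjusted p under 0.05. The contrasts were strain, sex, ethanol within each strain, conditioning within each strain, and the differences of these effects between strains, between conditioning states and between sexes. Every log2 value for strain is DBA/2J minus C57BL/6J, for sex male minus female, for ethanol ethanol minus saline, and for conditioning FC minus noFC. Differences of effects by strain are DBA/2J minus C57BL/6J, those by conditioning FC minus noFC, and those by sex male minus female.

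Groups of genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, for 33 lists of activity, stress, metabolic, receptor and cell-type genes. A second run estimated the correlation from the data. List p-values were adjusted over the 33 lists of a contrast, and members were also counted with the adjustment made over the list alone. Some genes stand in more than one list, such as Pdk4 and Klf15, which are both glucocorticoid-induced and FoxO targets. Transcript usage, the share of a gene's counts on each transcript, was tested with voom and diffSplice in limma (Simes p per gene) on rounded transcript counts. Transcripts needed at least 10 counts in at least 3 libraries and at least 5% of their gene's counts, which left 26822 transcripts of 9517 genes.

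The contrasts, tests, gene lists and most alternatives were fixed before the data were examined. So was the rule for naming genes. It took up to 8 genes per direction with the smallest p among those called, without genes that had no symbol, a symbol of Gm and digits or one ending in Rik, and for strain also the 5 largest differences per direction above a mean log2 CPM of 1. It added up to 4 members per list, the 5 genes with the smallest p for transcript usage, and, where useful, members of a set (Fos, Arc, Egr1, Npas4, Bdnf, Fkbp5, Sgk1, Per1, Gabra2, Nnt, Glo1, Alad, and for sex Xist and Ddx3y). Any other named gene was chosen after its values were seen. Further list members beyond 4 are such genes.

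The alternatives fixed in advance were DESeq2 1.42.0, other scaling, no filter on low counts, gene sums of the transcript counts, each strain fitted alone, the round of titles as a covariate, 2 surrogate variables from sva 3.50.0, the title number as a replicate block, other transcript filters and tests, and leaving out each library in turn. Alternatives chosen after seeing the data were the mean of the 15 tested choroid plexus markers as a covariate, leaving out 17 libraries with Ttr above 2000 CPM, and each round of titles alone. Leaving out the libraries high in Ttr kept only 1 library in the smallest group, fear-conditioned male C57BL/6J mice given ethanol. The list of choroid plexus markers cannot keep a call with that covariate, which is its own mean. Groupings drawn at random, 60 for gene results and 40 for transcript usage with the real one included, were fitted the same way. In simulated counts with the same design, changed genes were recovered for ethanol in C57BL/6J in 53.7% of cases at a log2 change of 0.25, 73.1% at 0.5 and 93.9% at 1, with 3.3% false calls. For the difference of ethanol effects between strains the shares were 34.3%, 64.2% and 83.3%, with 6.2% false calls. Simulated changes of transcript usage by strain gave 24.3% false calls, so single transcript calls are less firm than gene calls. R 4.3.3, Python 3.11.15 and pandas 2.3.3 were used. No library was left out of the fits reported first.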

Results

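Dorsal hippocampus RNA was measured in 31 libraries of C57BL/6J mice and 32 of DBA/2J mice, 31 from males and 32 from females. The strains differ in their response to ethanol and in learning, and the groups combined strain and sex with ethanol or saline and with fear conditioning or none. Total gene counts per library ran from 21027659 to 61631742, with a median of 26379948. Positions are on the mouse build GRCm38.

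The strain comparison asked which genes differ between DBA/2J and C57BL/6J hippocampus whatever the treatment. Gabra2, the alpha 2 subunit of the GABA-A receptor (ENSMUSG00000000560, chromosome 5, 70957597 to 71095849), stood at 220 ± 24 CPM (SD, n = 32) in DBA/2J and 97.2 ± 12.1 CPM (SD, n = 31) in C57BL/6J. Glo1, which clears methylglyoxal, stood at 175 ± 8.96 CPM against 92.5 ± 6.14, and Alad, an enzyme of heme synthesis, at 38.5 ± 3.35 against 13.7 ± 1.12. The log2 differences were 1.18 (SE 0.05, adjusted p = 1.5e-29) for Gabra2, 0.92 (SE 0.02, adjusted p = 2.9e-40) for Glo1 and 1.50 (SE 0.03, adjusted p = 3.3e-42) for Alad. Hdhd3, which lies beside Alad, was higher by 1.62 (SE 0.04), while Gpnmb, a membrane glycoprotein with a known DBA/2J mutation, was lower at -3.23 (SE 0.07). Of 19974 genes tested, 9986 were called, 5098 higher and 4888 lower in DBA/2J, and the median size of a called difference was 0.21. A larger than 2-fold difference was seen in 1036 genes, 550 higher and 486 lower.

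The strongest strain calls included several processed pseudogenes and their parent genes. Atp6v0c-ps2 (chromosome 6, 37806086 to 37806550), a copy of the proton pump gene Atp6v0c, was higher by 8.11 (SE 0.07, adjusted p = 4.1e-60), and Atp6v0c was lower at -2.07 (SE 0.03, adjusted p = 1.6e-50). Reads of near-identical copies are hard to assign, so the values of such pairs are uncertain. Other genes with the smallest p among the higher ones were Tpm3-rs7 (2.30), Rpsa-ps10 (4.88), Sfi1 (2.85), AC165951.1 (9.15), Eno1b (5.01), Scg5 (1.70), which encodes a secretory granule chaperone, and AC127331.2 (4.99). Among the lower ones they were Tceanc2 (-2.55), Pttg1 (-3.61), Hjurp (-1.82), Rpl21 (-2.29), Rps2 (-1.41), Sbsn (-4.25) and Fggy (-5.32). The largest differences above the level limit also included Rps15a-ps8 (8.13), Serpina3m (8.11) and Usf2-ps1 (7.69) on the higher side, and Pla2g2f (-6.11), Zfp970 (-6.02), Zfp125 (-5.83) and Mndal (-4.89) on the lower side. By gene type, 8137 of 15588 protein-coding genes, 490 of 1256 pseudogenes, 1349 of 3099 other non-coding genes and 10 of 31 genes outside the annotation were called. Differences over 8-fold were higher in DBA/2J for 108 pseudogenes and lower for 18, against 50 and 45 for protein-coding genes.

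Gene groups also differed between the strains. All 12 oligodendrocyte markers were lower in DBA/2J, with a median of -0.39; examples were the myelin genes Mal (-0.67, SE 0.09) and Mobp (-0.58, SE 0.08). Of 16 interferon and antigen presentation genes 11 were lower and 0 higher (12 and 1 adjusted over the list alone), with a median of -0.33 and H2-K1 at -1.05 (SE 0.05) and B2m at -0.41 (SE 0.05). Effects of DBA/2J variants on the assignment of reads to the build GRCm38 were not tested, so lower counts of such genes need not be lower expression. Of 12 genes of ethanol and aldehyde metabolism 7 were lower and 0 higher (8 and 0 adjusted over the list alone), led by the dehydrogenases Aldh7a1 (-0.82, SE 0.02) and Aldh1a1 (-0.56, SE 0.04). The list of genes with known differences between these strains, which counts Nnt under each of its 2 gene identifiers (0.21 and 0.23, SE 0.03 each), had 7 of 9 higher and 2 lower, among them Gpnmb. Camera gave these 4 lists adjusted p = 0.011, 0.011, 0.011 and 0.0065, in the order named, and 0 lists passed with an estimated correlation (adjusted p = 0.99, 0.99, 0.51 and 0.14 with an estimated correlation).

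For the other 29 lists the strain test gave no call. Adjusted p was 0.051 for dentate gyrus markers, of which 6 of 8 were lower, with C1ql2 at -1.46 (SE 0.05), Tdo2 at -0.93 (SE 0.06) and Prox1 at -0.29 (SE 0.05). It was 0.058 for endoplasmic reticulum chaperones, with 11 of 17 higher and 2 lower, such as Hyou1 (0.20, SE 0.02) and Xbp1 (0.25, SE 0.03). Immediate early genes gave 0.18 with 14 of 32 higher and 2 lower. Microglia markers gave 0.26, oligodendrocyte precursor markers 0.31, glucocorticoid-induced genes 0.32, nicotinic acetylcholine receptor subunits 0.40, energy stress and FoxO targets 0.68, meningeal and fibroblast markers 0.68, ribosomal proteins 0.71 and blood markers 0.89. The value was 0.95 for subunits of GABA-A and of ionotropic glutamate receptors, histone acetylation and DNA methylation enzymes, cholesterol biosynthesis, cytokines and NF-kB signalling, endothelial markers and choroid plexus markers. It was 0.97 for delayed activity genes, cytosolic heat shock genes, clock genes, the respiratory chain, and markers of astrocytes, CA1, CA3 and CA2, interneurons, thalamus, neocortex and striatum. Across all contrasts the median, the mean and the test had one sign in every called list, but differed in sign for 43 list tests without a call, such as the thalamus markers here (median -0.06, mean 0.06).

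Some single genes switched on by neuronal activity differed in level between the strains, although their lists were not called. Npas4 was higher in DBA/2J by 0.50 (SE 0.05, adjusted p = 3.8e-13), Fos by 0.35 (SE 0.06, adjusted p = 7.7e-07) and Arc by 0.17 (SE 0.05, adjusted p = 0.0059). Bdnf, a neurotrophin, was lower at -0.34 (SE 0.05, adjusted p = 2.7e-08), and so was Fkbp5, a regulator of the glucocorticoid receptor, at -0.17 (SE 0.04, adjusted p = 0.00037). Egr1 (0.10, adjusted p = 0.076), Per1 (0.08, adjusted p = 0.062) and Sgk1 (0.07, adjusted p = 0.46) were not called.

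Between the sexes the genes of the Y chromosome and the X inactivation transcript stood far apart. Ddx3y was at 67.8 ± 9.01 CPM (SD, n = 31) in males and 0.334 ± 0.393 CPM (SD, n = 32) in females, and Xist (chromosome X, 103460366 to 103483254) at 2.55 ± 2.31 CPM in males and 901 ± 77 in females. Kdm5d (8.30, SE 0.11), Uty (8.20, SE 0.16), Ddx3y (7.95, SE 0.15) and Eif2s3y (7.88, SE 0.14) were higher in males. Their X-linked relatives Eif2s3x (-0.60), Kdm6a (-0.46), Kdm5c (-0.33) and Ddx3x (-0.28), each with SE 0.02, were lower in males, as were Jpx (-0.37), Pbdc1 (-0.26) and the autosomal protocadherin Pcdhb6 (-0.41). Outside the sex chromosomes, genes higher in males included Arrdc2 (0.33, SE 0.05, adjusted p = 8.7e-05), Nfkbia (0.21, SE 0.04, adjusted p = 0.00096), Ddx4 (0.49, SE 0.09, adjusted p = 0.0012) and Polr3e (0.12, SE 0.02, adjusted p = 0.0035). In total 40 genes were called, 16 higher and 24 lower in males, of which 5 in each direction differed over 2-fold.

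Of the 33 lists 9 passed for sex, 6 up and 3 down in males, and 0 with an estimated correlation. Glucocorticoid-induced genes had 2 of 23 higher (5 adjusted over the list alone, among them Sgk1 at 0.29 and Ddit4 at 0.10), with camera adjusted p = 0.00052 and adjusted p = 0.68 with an estimated correlation. Endothelial (median 0.06, adjusted p = 0.0042), meningeal and fibroblast (median 0.26, adjusted p = 0.0042), microglia (median 0.03, adjusted p = 0.018), oligodendrocyte (median 0.07, adjusted p = 0.022) and blood markers (median 0.38, adjusted p = 0.022) were up. The respiratory chain (median -0.03, adjusted p = 9.6e-06), ribosomal proteins (median -0.02, adjusted p = 0.00052) and delayed activity genes (median -0.04, adjusted p = 0.035) were down. Every one of these 8 had adjusted p = 0.68 with an estimated correlation. With the choroid plexus mean as a covariate the meningeal and fibroblast median was 0.13 (adjusted p = 9e-04). The choroid plexus markers had positive values in 15 of 15 (0.19 to 0.92, median 0.55) but were not called as a list (adjusted p = 0.38).

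The ethanol comparison in C57BL/6J set 16 libraries of ethanol-treated mice against 15 given saline. Depp1, a target of FoxO factors that takes part in autophagy (ENSMUSG00000048489, chromosome 6, 116650609 to 116652794), fell from 2.22 ± 0.496 CPM (SD, n = 15) to 1.06 ± 0.474 CPM (SD, n = 16), a log2 change of -1.15 (SE 0.14, adjusted p = 4.5e-07). Arc, a synaptic immediate early gene (ENSMUSG00000022602, chromosome 15, 74669083 to 74672570), fell from 247 ± 45.8 to 182 ± 34.3 CPM, a change of -0.45 (SE 0.07, adjusted p = 0.0017). Pik3ip1, an inhibitor of PI3 kinase, rose from 32.6 ± 1.98 to 37.8 ± 2.75 CPM, a change of 0.21 (SE 0.04, adjusted p = 0.0017). On the log2 CPM scale Depp1 lay below the saline mean in 15 of 16 ethanol libraries, Arc in 15, and Pik3ip1 above it in 16. In total 18 genes were called, 7 higher and 11 lower, and 842 had an unadjusted p under 0.05 where 999 are expected by chance. The other named genes that rose were Nrarp, a Notch target (0.24), Hmgb2 (0.40), Sox12 (0.17), Exo5 (0.19), the p53 target Bbc3 (0.29) and Fam214a (0.13). Those that fell were Trib1 (-0.29), Zfp366 (-0.38), Ier3 (-0.49), Dusp5 (-0.28), Spry4 (-0.23) and Egr2 (-0.53), and a heat shock list member, Dnajb5 (-0.17).

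Immediate early genes were lower as a group after ethanol in C57BL/6J. Of 32 tested, 4 fell (Arc, Egr2, Trib1 and Dusp5) and 0 rose, or 11 and 0 adjusted over the list alone, and 26 had a negative value, with a median of -0.11. Camera gave adjusted p = 8.2e-15, and adjusted p = 0.027 with an estimated correlation. Fos (-0.27, SE 0.08, adjusted p = 0.55), Egr1 (-0.27, SE 0.07, adjusted p = 0.18) and Npas4 (-0.22, SE 0.07, adjusted p = 0.58) were not called over all genes. Energy stress and FoxO targets were up, with 1 of 16 called (Pik3ip1), a median of 0.05, adjusted p = 0.0001, and adjusted p = 0.029 with an estimated correlation. Depp1, also a target of FoxO factors, is not in this list and fell. Another 5 lists passed only at the preset correlation, all down. These were heat shock genes (1 of 18 called, median -0.06, adjusted p = 1.2e-07, and adjusted p = 0.16 with an estimated correlation) and glucocorticoid-induced genes (0 of 23 called, 2 adjusted over the list alone, median -0.06, adjusted p = 0.00014, and adjusted p = 0.43 with an estimated correlation). Delayed activity genes (median -0.04, adjusted p = 0.0049), endoplasmic reticulum chaperones (median -0.04, adjusted p = 0.019) and the respiratory chain (median -0.02, adjusted p = 0.028) gave adjusted p = 0.31, 0.81 and 0.81 with an estimated correlation. Gabra2 (0.00), Bdnf (-0.10), Fkbp5 (-0.07), Per1 (-0.10) and Sgk1 (-0.23) were not called (adjusted p = 1 each). Depp1, Arc, Pik3ip1 and Trib1 were called whichever of the 31 libraries was left out, but the count of genes dropped to 10 without library B6_F_FC_SAL_319, and with the first or the second round of titles alone it was 0 and 1.

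**Figure D1:**
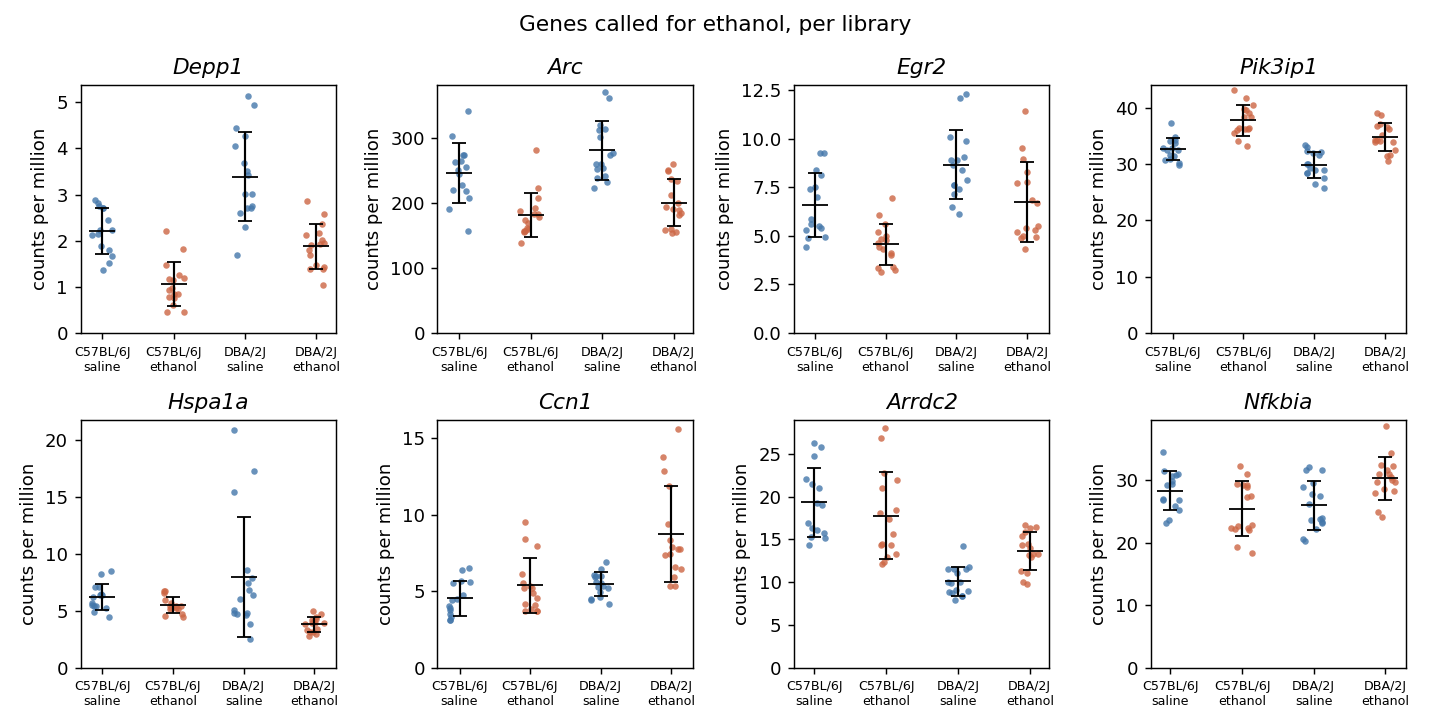
CPM of 8 genes in each library, by strain and drug, with the mean and SD as bars (n = 15 for C57BL/6J with saline, 16 in the other groups). Depp1 and Arc were lower and Pik3ip1 higher with ethanol in both strains, while Arrdc2 and Nfkbia rose in DBA/2J and differed between the strains in their ethanol effect.

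In DBA/2J, 16 libraries from ethanol-treated mice were set against 16 from saline-treated ones. Fam214a rose from 46.1 ± 2.92 to 54.5 ± 3.64 CPM (SD, n = 16 each), a log2 change of 0.24 (SE 0.03, adjusted p = 1.8e-07). Ccn1, a matricellular immediate early gene (chromosome 3, 145646976 to 145649981), rose from 5.45 ± 0.781 to 8.75 ± 3.14 CPM (0.64, SE 0.10, adjusted p = 0.00013). Arc fell from 282 ± 44.9 to 201 ± 36 CPM (-0.49, SE 0.07, adjusted p = 7.4e-05) and Depp1 fell by 0.86 (SE 0.12, adjusted p = 5.9e-05). On the log2 CPM scale Arc lay below the saline mean in 16 of 16 ethanol libraries, Depp1 in 16, and Fam214a above it in 16. In total 59 genes were called, 27 higher and 32 lower, and 1669 had an unadjusted p under 0.05. The arrestin family genes Arrdc3 (0.37) and Arrdc2 (0.43), Pik3ip1 (0.22), Nrarp (0.22), Dclre1a (0.24) and Zfp867 (0.44) were the other named genes that rose. Dnase1l2 (-0.33), Jmjd6 (-0.20) and P4ha1 (-0.25) fell together with several chaperone genes.

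Those chaperone genes belong to the heat shock list, which was lower as a group in DBA/2J after ethanol. Of 18 members, 6 fell and 0 rose, or 15 and 0 adjusted over the list alone, and all 18 had a negative value. Hspa1a (chromosome 17, 34969190 to 34972156) went from 7.96 ± 5.26 to 3.83 ± 0.641 CPM (-1.02, SE 0.17, adjusted p = 0.00044), Hspa1b from 9.66 ± 6.76 to 4.81 ± 0.74 (-0.96, SE 0.17, adjusted p = 0.0016) and Dnajb1 from 55.7 ± 10.1 to 42.6 ± 4.23 (-0.39, SE 0.06, adjusted p = 7.4e-05). Hspa1a and Hspa1b are near-identical neighbours, so their split of reads is uncertain. The saline means rest in part on 3 libraries of the second round, DBA_M_FC_SAL_320, DBA_F_FC_SAL_321 and DBA_F_noFC_SAL_325, with Hspa1a at 20.9, 17.3 and 15.5 CPM, Hspa1b at 24.2, 23.4 and 20.8, and Dnajb1 at 72.5, 79.4 and 73.3. The medians went from 6.24 to 3.93 CPM for Hspa1a, 6.85 to 4.85 for Hspa1b and 52.5 to 42.2 for Dnajb1, and all 16 ethanol libraries lay below each saline median. Hsph1 (-0.20), Fkbp4 (-0.13) and Stip1 (-0.16) also fell. Camera gave adjusted p = 7.6e-28, and adjusted p = 0.00033 with an estimated correlation. The Hspa1a change was -0.41 (adjusted p = 0.2) in the first round of titles and -1.41 (adjusted p = 0.016) in the second, and between -1.09 and -0.85 when any one library was left out.

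Energy stress and FoxO targets were up in DBA/2J, with 3 of 16 called, Arrdc3, Pik3ip1 and Txnip (0.44, SE 0.09), adjusted p = 1.8e-06, and adjusted p = 0.0063 with an estimated correlation. Depp1, a FoxO target outside this list, fell in DBA/2J too. Glucocorticoid-induced genes were up with 3 of 23 called, Arrdc2, the mTOR inhibitor Ddit4 (0.20) and Nfkbia (0.22), or 4 adjusted over the list alone, a median of 0.10 and adjusted p = 2.1e-06, but adjusted p = 0.22 with an estimated correlation. Immediate early genes had 2 members that fell, Arc and Dusp6 (-0.25), and 2 that rose, Ccn1 and Gadd45g (0.26), or 10 and 3 adjusted over the list alone, with a median of -0.08, adjusted p = 3.4e-05, and adjusted p = 0.27 with an estimated correlation. Endoplasmic reticulum chaperones were down, with Ddit3 (-0.23) called, 8 of 17 adjusted over the list alone, adjusted p = 6e-11, and adjusted p = 0.14 with an estimated correlation. Delayed activity genes were down with Spry4 (-0.24) and Spry2 (-0.21) called (adjusted p = 0.011, and 0.3 as adjusted p with an estimated correlation). Cholesterol biosynthesis was up with 0 called, 3 adjusted over the list alone, among them Insig1 (0.18), adjusted p = 1.4e-08, and adjusted p = 0.15 with an estimated correlation.

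Another 10 lists passed in DBA/2J at the preset correlation alone. Ribosomal proteins (36 of 36 negative, median -0.05, adjusted p = 2.8e-10), the respiratory chain (median -0.06, adjusted p = 1.2e-07), GABA-A receptor subunits (median -0.03, adjusted p = 0.022) and dentate gyrus markers (median -0.06, adjusted p = 0.039) were down. Markers of oligodendrocyte precursors (median 0.13, adjusted p = 0.0005), oligodendrocytes (median 0.15, adjusted p = 0.00095), microglia (median 0.04, adjusted p = 0.022), meninges and fibroblasts (median 0.20, adjusted p = 0.022) and endothelium (median 0.05, adjusted p = 0.025), with ethanol metabolism (median 0.02, adjusted p = 0.027), were up. Their adjusted p with an estimated correlation lay between 0.15 and 0.62. The count of 59 genes was 14 without the 17 libraries with Ttr above 2000 CPM, 63 in the first round of titles alone (87.3% higher, 10 shared with the 59), 10 in the second alone (10% higher, 7 shared) and 110 with DESeq2. All 59 kept their sign in each round. Within 1 round the drug coincides with the title letter, so a round alone cannot tell them apart.

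The ethanol effects of the strains overlapped. Called in both were Fam214a, Pik3ip1, Nrarp and Bbc3 on the higher side, where 0.0095 are expected by chance, and Depp1, Arc and Spry4 on the lower side, where 0.018 are expected, and 0 genes were called in opposite directions (Fisher's exact p = 4.2e-14). All 18 genes called in C57BL/6J had the same sign in DBA/2J, and 49 of the 59 called in DBA/2J had the same sign in C57BL/6J. The strains share no libraries. Across all genes the effects correlated weakly (Pearson r 0.054, Spearman rho 0.121, with genes that are not independent replicates). Fisher's test also treats genes as independent, so its p-value can overstate the evidence for an overlap.

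The difference of the ethanol effects between the strains was called for 2 genes, both from the glucocorticoid-induced list. Arrdc2, an arrestin family gene (chromosome 8, 70835129 to 70839720), went from 10.1 ± 1.7 to 13.7 ± 2.23 CPM in DBA/2J (SD, n = 16 each) and from 19.3 ± 4.05 (n = 15) to 17.8 ± 5.06 CPM (n = 16) in C57BL/6J, a difference of 0.59 (SE 0.11, adjusted p = 0.022). Nfkbia, the inhibitor of NF-kB (chromosome 12, 55489410 to 55492647), went from 26 ± 3.92 to 30.4 ± 3.44 CPM in DBA/2J and from 28.4 ± 3.21 to 25.5 ± 4.37 in C57BL/6J, a difference of 0.40 (SE 0.08, adjusted p = 0.034). Ddit4 differed by 0.29 (adjusted p = 0.15) and Sgk1 by 0.49 (SE 0.14, adjusted p = 1). The list had 22 of 23 positive differences, a median of 0.14 and adjusted p = 6.3e-12, with 5 genes called adjusted over the list alone, but adjusted p = 0.11 with an estimated correlation. Heat shock genes differed the other way (median -0.09, 3 adjusted over the list alone, adjusted p = 7.5e-08, and adjusted p = 0.22 with an estimated correlation), with Hspa1a at -0.84 (SE 0.24, adjusted p = 1), so the lower level in DBA/2J was not shown to be larger than in C57BL/6J for that gene. For Arc the difference was -0.04 (SE 0.10, adjusted p = 1). The Arrdc2 call held in 57 and the Nfkbia call in 30 of 63 fits that left out 1 library, and in the second round of titles alone 0 genes were called. The fit without the libraries with Ttr above 2000 CPM and that of the first round each held a group with 1 library, so sizes are compared. The differences were 0.52, 0.56 and 0.60 for Arrdc2 without high Ttr, in the first round and in the second. For Nfkbia they were 0.39, 0.49 and 0.31 in that order.

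Another 9 lists were called for that difference, 0 of them with an estimated correlation. Up were meningeal and fibroblast (median 0.36, adjusted p = 0.0011), endothelial (median 0.09, adjusted p = 0.00053) and oligodendrocyte markers (median 0.13, adjusted p = 0.018), cholesterol biosynthesis (median 0.05, adjusted p = 0.00054) and immediate early genes (median 0.05, adjusted p = 0.047). Down were ribosomal proteins (median -0.05, adjusted p = 8.5e-06), endoplasmic reticulum chaperones (median -0.07, adjusted p = 0.00053), the respiratory chain (median -0.03, adjusted p = 0.018) and GABA-A receptor subunits (median -0.04, adjusted p = 0.02). Their adjusted p with an estimated correlation lay between 0.6 and 0.88, and with the choroid plexus mean as a covariate the immediate early genes lost their call (adjusted p = 0.053).

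Fear conditioning was compared with no conditioning in each strain, to find genes that respond to training. In C57BL/6J, Fos (chromosome 12, 85473890 to 85477273) stood at 23.1 ± 4.52 CPM (SD, n = 15) after conditioning and 17.2 ± 2.86 CPM (SD, n = 16) without it, a log2 difference of 0.42 (SE 0.08, adjusted p = 0.073). Arc stood at 239 ± 54.6 against 190 ± 35.1 CPM (0.34, SE 0.07, adjusted p = 0.12), and Ccn1 differed by 0.46 (SE 0.10, adjusted p = 0.15). On the log2 CPM scale Fos lay above the noFC mean in 14 of 15 conditioned libraries and Arc in 11. The edgeR fit called 0 genes, with 786 at an unadjusted p under 0.05, and DESeq2 called 6, among them Fos, Arc and Ccn1, and also Apold1, which was chosen for naming after its values were seen. As a group, immediate early genes were up, with 30 of 32 positive, a median of 0.17, 0 called over all genes and 16 of 32 adjusted over the list alone, led by Fos, Arc, Ccn1, Btg2 (0.15) and Klf4 (0.34). Camera gave adjusted p = 6.8e-24, and adjusted p = 0.0012 with an estimated correlation. Egr1 (0.23) and Npas4 (0.18) had adjusted p = 1 over all genes. Fos was called in 4 of the 31 fits that left out 1 library, and 5 of those fits called any gene, with 4 genes without B6_M_FC_EtOH_322, 3 without B6_F_noFC_SAL_311, 2 without B6_F_noFC_EtOH_315 and 1 without B6_M_FC_EtOH_310 or B6_M_noFC_EtOH_310.

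Another 8 lists passed for conditioning in C57BL/6J at the preset correlation alone (adjusted p = 0.59 or 0.62 each with an estimated correlation). Meningeal and fibroblast markers (median 0.31, adjusted p = 0.00022), interferon genes (median 0.09, adjusted p = 0.022) and glucocorticoid-induced genes (median 0.04, adjusted p = 0.034) were up. The respiratory chain (median -0.03, adjusted p = 5.8e-05), ribosomal proteins (median -0.03, adjusted p = 7.4e-05), dentate gyrus markers (median -0.08, adjusted p = 0.005), GABA-A receptor subunits (median -0.05, adjusted p = 0.013) and cholesterol biosynthesis (median -0.02, adjusted p = 0.049) were down. With the choroid plexus mean as a covariate the calls of interferon genes (median 0.05, adjusted p = 0.093), glucocorticoid-induced genes (median 0.02, adjusted p = 0.075) and GABA-A receptor subunits (median -0.04, adjusted p = 0.052) were lost.

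**Figure D2:**
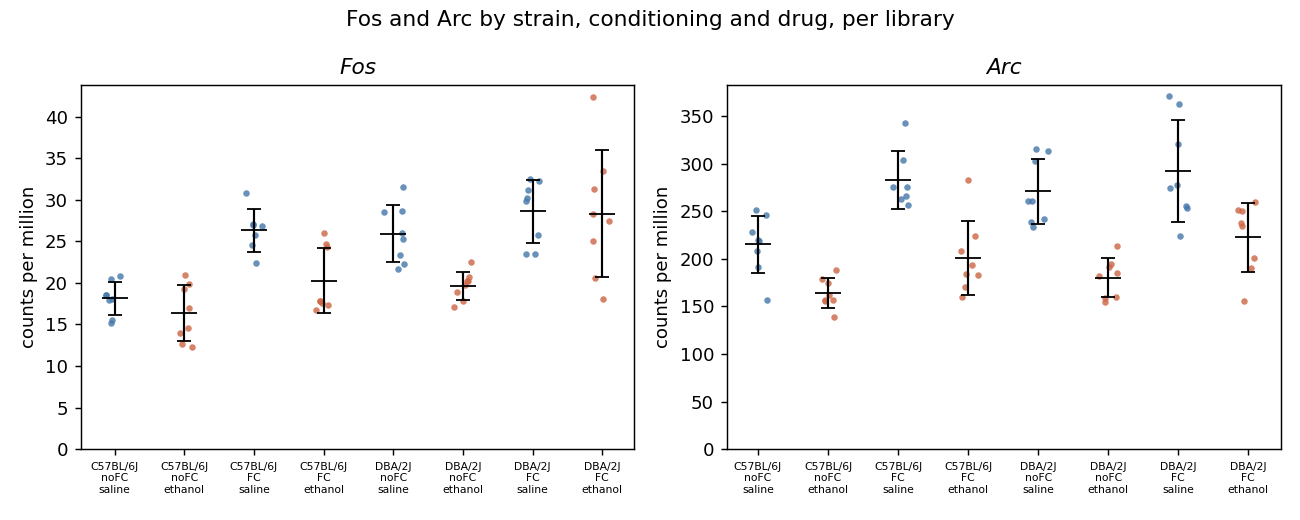
CPM of Fos and Arc in each library by strain, conditioning and drug, with the mean and SD as bars (n = 7 for fear-conditioned C57BL/6J with saline, 8 in the other groups). Fear-conditioned C57BL/6J with saline had the highest means of that strain, 26.3 for Fos and 283 for Arc.

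In DBA/2J, Fos stood at 28.4 ± 5.81 CPM after conditioning and 22.8 ± 4.17 CPM without it (SD, n = 16 each), a difference of 0.34 (SE 0.08, adjusted p = 1). The edgeR fit called 0 genes, with 670 at an unadjusted p under 0.05, and DESeq2 called 0 as well. Immediate early genes were up, with 22 of 32 positive, a median of 0.05, 7 called adjusted over the list alone, among them Btg2 (0.13), Ccn1 (0.35) and Arc (0.21), and adjusted p = 2.3e-05, but adjusted p = 0.43 with an estimated correlation. The difference between the strains in this list was -0.08 in the median, with 30 of 32 negative, adjusted p = 0.0003, and adjusted p = 0.61 with an estimated correlation. Over all genes the difference of the conditioning effects was called for 0 genes in edgeR, with 725 at an unadjusted p under 0.05, and for 0 in DESeq2. The list test passed for 11 lists there and for 0 with an estimated correlation, and 5 of the 11 lost their call with the choroid plexus mean as a covariate (heat shock genes, clock genes, histone acetylation and DNA methylation enzymes, and markers of microglia and choroid plexus). The loss for the choroid plexus markers was fixed in advance, since the covariate is their mean. With conditioning in DBA/2J, heat shock genes (median 0.06, adjusted p = 9.2e-05) and meningeal and fibroblast markers (median 0.19, adjusted p = 0.012) were up as well. Microglia (median -0.05, adjusted p = 9.2e-05), oligodendrocyte (median -0.12, adjusted p = 0.0074), astrocyte (median -0.04, adjusted p = 0.013) and endothelial markers (median -0.03, adjusted p = 0.03) and ribosomal proteins (median -0.02, adjusted p = 0.02) were down. These lists had adjusted p = 0.43 or 0.66 with an estimated correlation. Of the 3 libraries high in Hspa1a named above, 2 were conditioned, and on the log2 CPM scale 7 of 16 conditioned libraries lay above the noFC mean for Hspa1a and 8 for Hspa1b. With the choroid plexus mean as a covariate the meningeal and fibroblast markers turned to a median of -0.08 (adjusted p = 0.2), and ribosomal proteins lost their call (adjusted p = 0.06).

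Choroid plexus markers were also higher in conditioned DBA/2J libraries, with a median of 1.68, 9 of 15 called adjusted over the list alone, adjusted p = 9.9e-09, and adjusted p = 0.43 with an estimated correlation. Ttr, the transthyretin gene of the choroid plexus (chromosome 18, 20665280 to 20674321), differed by 2.22 (SE 0.78), Tmem72 by 2.61 and Kcnj13 by 2.26. Over all 63 libraries of both strains, Ttr ranged from 12.3 to 11000 CPM within these dissections of hippocampus. In DBA/2J the means were 2120 ± 2840 CPM with conditioning and 1300 ± 2160 CPM without (SD, n = 16 each), so the spread between libraries exceeded the difference of the means. The fitted difference compares the log2 of fitted group levels, averaged over the groups of sex and drug. It need not match the ratio of the CPM means, nor the difference of the mean log2 CPM, which was 9.14 with conditioning and 7.45 without. On that scale 10 of 16 conditioned libraries lay above the noFC mean. In C57BL/6J the list had a median of -0.03 (adjusted p = 0.1).

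**Figure D3:**
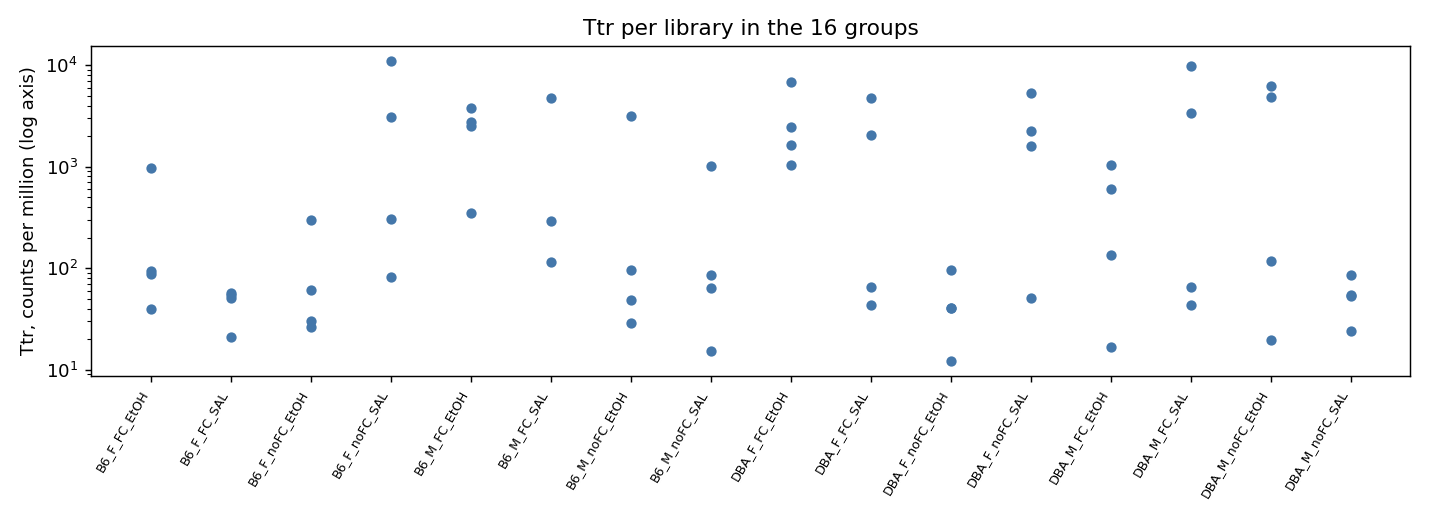
Ttr in each of the 63 libraries on a log axis of CPM, in the 16 groups of strain, sex, conditioning and drug. Values ran from 12.3 to 11000 CPM, and 17 libraries lay above 2000 CPM.

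**Figure D4:**
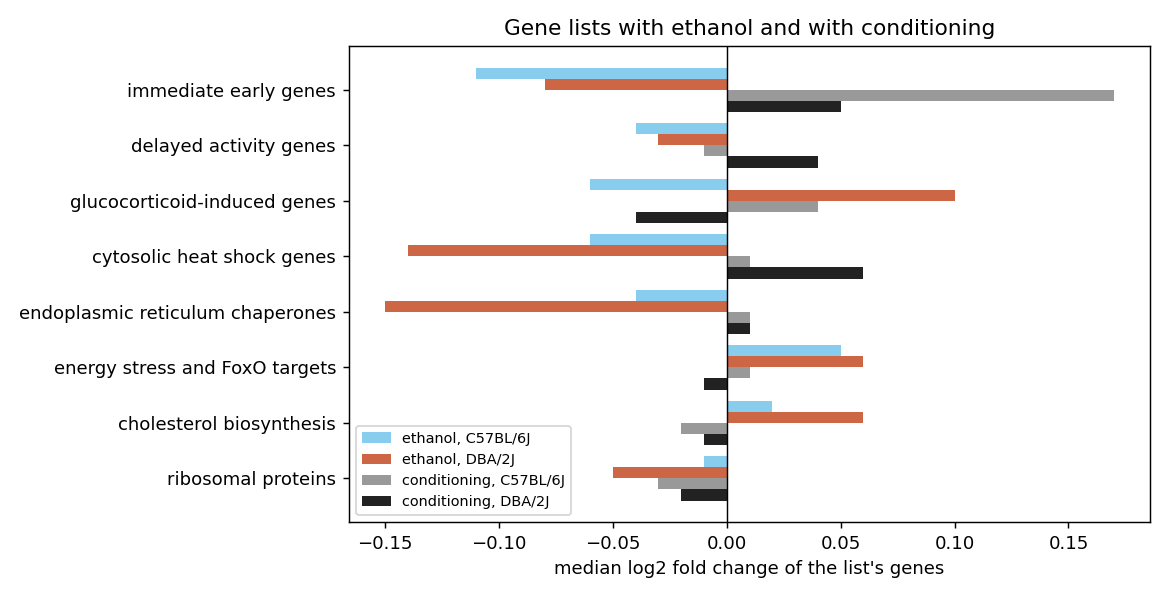
Median log2 difference of 8 gene lists for ethanol and for conditioning in each strain, with a line at 0. Immediate early genes had a median of -0.11 with ethanol and 0.17 with conditioning in C57BL/6J, and heat shock genes -0.14 with ethanol in DBA/2J.

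Whether conditioning changed the ethanol effect was tested as the difference of the effects. Fos differed by -0.23 (SE 0.17, adjusted p = 1) in C57BL/6J and 0.38 (SE 0.16, adjusted p = 0.87) in DBA/2J, and Arc by -0.12 (SE 0.15, adjusted p = 1) and 0.20 (SE 0.14, adjusted p = 0.93). The edgeR fit called 0 genes in each strain, with 497 and 1115 at an unadjusted p under 0.05, and DESeq2 called 0 in each. Among the 6 lists called in C57BL/6J were choroid plexus markers (median 2.36, adjusted p = 3.4e-09), ethanol metabolism (median 0.08, adjusted p = 0.0077) and dentate gyrus markers (median 0.15, adjusted p = 0.011). Among the 8 in DBA/2J were dentate gyrus markers (median -0.25, adjusted p = 6.6e-05), neocortex markers (median 0.55, adjusted p = 0.00039) and ribosomal proteins (median 0.06, adjusted p = 0.0029). With an estimated correlation 0 lists passed in either strain, and with the choroid plexus mean as a covariate 1 of the 6 in C57BL/6J was kept, the dentate gyrus markers, and all 8 in DBA/2J. Among those not kept, the choroid plexus markers could not keep their call, since the covariate is their mean.

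Differences of effects between the sexes were also tested. The ethanol effect differed between males and females for 0 genes in edgeR, with 1011 at an unadjusted p under 0.05, and for 0 in DESeq2, and 6 lists passed. These included choroid plexus markers (median 2.45, 15 of 15 adjusted over the list alone, adjusted p = 1.4e-07), ribosomal proteins (median 0.07, adjusted p = 2e-10) and the respiratory chain (median 0.07, adjusted p = 8.3e-08), each with adjusted p = 0.81 with an estimated correlation, and 3 of the 6 were kept with the choroid plexus covariate. The loss for the choroid plexus markers was again fixed in advance. The conditioning effect differed for 0 genes in edgeR at a smallest adjusted p of 0.099, but 3667 genes had an unadjusted p under 0.05 where 999 are expected, and DESeq2 called 426. Oligodendrocyte markers had positive differences in 12 of 12, with a median of 0.36, 4 called adjusted over the list alone, such as Aspa (0.48, SE 0.14) and Ermn (0.41, SE 0.14), adjusted p = 5.4e-06, and adjusted p = 0.63 with an estimated correlation. Neocortex markers (median 0.50, 4 of 7 adjusted over the list alone, with Cux2 at 0.50 and Ccn2 at 0.79) gave adjusted p = 0.0086, and dentate gyrus markers (median -0.24, 4 of 8 lower, with C1ql2 at -0.25 and Prox1 at -0.24) gave adjusted p = 0.0002, each with adjusted p = 0.58 with an estimated correlation. The list test also passed for striatum (median 0.27, adjusted p = 0.031) and CA1 markers (median -0.17, adjusted p = 0.031), but 0 of the 11 lists called passed with an estimated correlation, and with the choroid plexus mean as a covariate these gave adjusted p = 0.052 and 0.15. Leaving out library DBA_M_noFC_EtOH_312 raised the edgeR count to 297, leaving out B6_M_noFC_EtOH_310 to 146, DBA_M_FC_EtOH_324 to 57 and DBA_M_FC_SAL_312 to 1, while each other such fit called 0.

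Transcript usage separated the strains strongly. Transcript Pdxdc1-215 made up 90.8 ± 1.79% (SD, n = 32) of its gene's estimated counts in DBA/2J and 18.1 ± 1.6% (SD, n = 31) in C57BL/6J (adjusted p = 7.9e-119), Dap3-201 61 ± 2.86% against 21.2 ± 1.68%, and Ppib-201 94 ± 0.677% against 52.2 ± 3.46%. Transcript ENSMUST00000119158 of Tpm3 made up 21 ± 2.03% against 5.19 ± 0.625%. Of 9517 genes tested, 2443 were called, with 3313 at an unadjusted p under 0.05. Simulated counts gave 24.3% false calls for this contrast (27 genes). They held far fewer changed genes than the 2443 called here, so this share does not carry over to the real calls. Reads of both strains were assigned on the build GRCm38, and effects of DBA/2J variants on transcript or gene counts were not tested. Of 9452 genes tested for both usage and level, 2423 were called for usage, of which 1598 were also called for level and 825 were not.

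For the treatments, usage was called for 82 genes with ethanol in C57BL/6J, 130 with ethanol in DBA/2J, 53 with conditioning in C57BL/6J and 49 with conditioning in DBA/2J. Random regroupings of the same libraries called as many in 22, 11, 36 and 39 of 40 cases, in that order, so these counts do not exceed chance. Smallest p with ethanol in DBA/2J had Sergef, where Sergef-201 made up 20.2 ± 3.44% with ethanol and 12.1 ± 4.24% with saline (SD, n = 16 each, adjusted p = 3e-11), and Rsrp1, with Rsrp1-204 at 83.4 ± 3.4% and 73.4 ± 6.42% (adjusted p = 2e-09). In C57BL/6J the first was Fgfr1, with transcript ENSMUST00000119398 at 11.2 ± 3.16% and 6.41 ± 4.35% (adjusted p = 0.00048). With conditioning they were Jakmip1 (adjusted p = 0.0054) in C57BL/6J and Adora3 (adjusted p = 0.00025) in DBA/2J.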

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

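The tests that were chosen only after the results were seen are the gene sums for the pseudogenes, the choroid plexus covariate, the comparison of the title rounds, and the random regroupings, except the one on small p-values for conditioning by sex. A few libraries stood apart from the other 3 of their group. Arc was at 7.29 log2 CPM in library DBA_F_FC_EtOH_321 (others 7.9 to 8.02), and Fos at 4.07 in B6_M_FC_EtOH_322 (others 4.6 to 4.7). Depp1 was at 0.02 in that same library (others 0.29 to 0.34) and at 1.2 in B6_M_noFC_SAL_310 (others 1.48 to 1.53). Arrdc2 was at 3.55 in DBA_M_noFC_SAL_320 (others 3.15 to 3.2), and total counts were 34.4 M in DBA_F_noFC_EtOH_317 (others 25.2 to 26.6). These are 6 of 150 tests of a group, where chance gives about 1 in 20, or 7.5.

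Arrdc2 and Nfkbia stand out because their ethanol effects differed between the strains, by 0.59 and 0.40 on the log2 scale. Over the glucocorticoid-induced genes the median effect was -0.06 in C57BL/6J and 0.10 in DBA/2J, a median difference of 0.14. The median difference was 0.20 and 0.15 in the rounds of titles, so a single round does not account for it as the whole cause. It was 0.14 with the choroid plexus mean as a covariate and 0.11 with the endothelial mean. Marker means may correct for a tissue only in part, so neither tissue is excluded as a cause. With the endothelial covariate Arrdc2 stayed at 0.60 (adjusted p = 0.03), while Nfkbia went to 0.36 (adjusted p = 0.18) and lost its call. A strain difference in the stress hormone response to ethanol was not tested and stays open. Fkbp5, a target of the glucocorticoid receptor in that list, stood at -0.03 (SE 0.06) with ethanol in DBA/2J and differed between the strains by 0.04 (SE 0.08), and the list test lost its call with an estimated correlation.

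Among the strain calls, pseudogenes named after a tested parent and changed over 8-fold made 13 pairs. In 8 of them, 61.5%, the fitted change of the parent had the other sign (exact binomial p = 0.58), but Rpl21 is the parent in 2 pairs and Skiv2l, with one of the 8 signs, did not change (0.00, adjusted p = 0.98). Of 12 distinct parents 9 were called, and 6 of these moved the other way (exact binomial p = 0.51). Atp6v0c-ps2 went from 0.273 ± 0.149 CPM (SD) in C57BL/6J to 71.3 ± 6.19 in DBA/2J while Atp6v0c went from 137 ± 11.2 to 32.7 ± 2.34, and their sum from 137 to 104 CPM. Parent reads placed on a copy and a change of the pseudogene alone cannot be told apart with so few pairs, and in 2 pairs the parent changed the other way by 0.5 to 1.5 of the pseudogene's change in CPM. Usf2 rose by 4.31 CPM beside 4.97 for Usf2-ps1, so that pair goes against reads moved from the parent. All 7 of the 13 pseudogenes that were measured in the transcript sums (100%) kept direction and call, so for these the change is not confined to the gene counts. The other pseudogenes had no value there. Both sets of counts come from the same libraries, so wrongly placed reads are not excluded. DBA/2J variants against the reference were not tested and stay open.

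The excess of small p-values for conditioning by sex, 3667 genes at an unadjusted p under 0.05, went with marker lists of neighbouring regions. Across the 63 libraries, each minus its group mean, the neocortex and striatum mean went against the dentate gyrus and CA1 mean (Pearson r -0.66, Spearman rho -0.64, permutation p = 1e-05 each, the smallest that 1e+05 permutations can give). The correlation was -0.65 without the 2 farthest libraries, -0.67 in the first round of titles and -0.57 in the second. Of the markers listed, 7 of 8 for neocortex, 8 of 8 for striatum, 8 of 8 for dentate gyrus and 6 of 7 for CA1 passed the count filter, so these libraries express most of them. Unequal amounts of neighbouring tissue between libraries are therefore a candidate explanation, but a sex difference in the response to training stays open. With 2 surrogate variables the count was 605, and one of these variables followed the choroid plexus mean (Pearson r 0.78, Spearman rho 0.78, permutation p = 1e-05 each, r 0.76 without the 2 farthest libraries, 0.77 and 0.80 in the rounds), so this drop does not single out neighbouring tissue. With the choroid plexus mean as a covariate 2612 genes remained under that limit, and 8 of the 11 called lists were not kept. The loss of the choroid plexus list was fixed in advance, since the covariate is the mean of its markers. A mean of markers may correct for a tissue only in part, so choroid plexus tissue is not excluded as the cause. Of 60 groupings, the real one included, 2 gave as many genes at an unadjusted p under 0.05, the other with 3990. The share is under 0.05 by a narrow margin, so chance is not excluded.

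Libraries were also regrouped at random, 60 times for gene counts with the real grouping included. In some contrasts only the real one of the 60 groupings gave as many called genes. These were strain (9986 genes, highest other 2076), sex (40, highest other 30), ethanol in C57BL/6J (18, highest other 1), ethanol in DBA/2J (59, highest other 4) and ethanol by strain (2, highest other 1). That share, 1 of 60, is the smallest these groupings can give. The real differences stayed in the regrouped data and can widen the spread there, so the other counts may be too low. These draws alone therefore do not exclude chance. For ethanol by strain the result rests on 2 genes, and 34 of 63 fits without 1 library gave counts beyond 1.5 times. By genes at an unadjusted p under 0.05, as many arose in 1 grouping for strain, 20 for sex (1094 real), 22 for ethanol in C57BL/6J (842), 12 for ethanol in DBA/2J (1669) and 35 for ethanol by strain (720), so apart from strain the excess lies in the few genes called. Where 0 genes were called all 60 groupings give as many by construction, which says nothing about chance; there the highest others were 1 and 199 for conditioning in C57BL/6J and DBA/2J, 2207 for conditioning by strain, 95 and 4 for ethanol by conditioning, 103 for ethanol by sex and 345 for conditioning by sex. In each of these contrasts the median of the other groupings was 0 and 3 to 6 of them called any gene, so the few that call 199 to 2207 genes are extreme draws. What set those draws apart was not tested. The libraries did hold structure besides their groups. The first principal component held 25.9% of the variance within groups and followed the choroid plexus mean (Pearson r 0.95, Spearman rho 0.95, permutation p = 1e-05 each, the smallest possible, r 0.94 without the 2 farthest libraries and 0.95 in each round), and 389 genes were called between the rounds of titles. For transcript usage, of 40 groupings, only the real one gave as many as the 2443 for strain (highest other 284). Other groupings often gave as many for ethanol in C57BL/6J (82 real, 22 as many, highest other 189), ethanol in DBA/2J (130, 11, 344), conditioning in C57BL/6J (53, 36, 435) and conditioning in DBA/2J (49, 39, 215), so these counts do not exceed chance.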

How the results depend on the processing

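The choroid plexus covariate, the removal of libraries high in Ttr and the rounds of titles alone were chosen after the data were seen; for every change the cause was not tested, except that a round alone or fewer libraries hold fewer samples. The strain count stayed within 1.5 times in every setting run (7070 to 10649). With DESeq2 the counts were 110 for ethanol in DBA/2J, 6 for ethanol by strain, 6 for conditioning in C57BL/6J and 426 for conditioning by sex. Ethanol in DBA/2J gave 33 genes without the filter on low counts, 26 with the strain fitted alone and 126 with 2 surrogate variables. The fit without libraries high in Ttr held a group with 1 library, so its counts are a weak guide. Conditioning in C57BL/6J gave 1 gene (Fos) with the strain fitted alone, 2 with the title round as a covariate, 5 with 2 surrogate variables and 2 (Fos and Arc) with the choroid plexus covariate. Conditioning in DBA/2J gave 1 (Fos) with 2 surrogate variables. In the first round of titles alone the counts were 16 for sex, 0 for ethanol in C57BL/6J, 0 for ethanol by strain and 40 for ethanol by sex, and in the second alone 22 for sex, 1 for ethanol in C57BL/6J, 10 for ethanol in DBA/2J and 0 for ethanol by strain. With gene sums of the transcript counts ethanol by sex gave 1, and Nnt in the strain comparison was reversed for one identifier, at -0.13 (adjusted p = 0.57). Whether title numbers pair the libraries was not settled. Of 93 pairs of the same number 32 (34.4%) correlated above 0.1, and the median was 0.04 against -0.058 for other numbers of the same strain and sex. Of 63 libraries 27 correlated best with their own number among those of their strain and sex. Group means were subtracted first, which pushes libraries of the same group, all of other numbers, toward negative correlations. Both comparisons therefore favour the own number even without pairing and cannot settle it. As a replicate block the title numbers gave 109 genes for ethanol in DBA/2J, where the main fit gave 59, and 4 for ethanol by strain, where it gave 2.

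For transcript usage, in the order ethanol in C57BL/6J, ethanol in DBA/2J, conditioning in C57BL/6J and conditioning in DBA/2J, counts were 394, 409, 251 and 327 without the share filter and 29, 57, 10 and 21 with the replicate block. The F test gave 37 for ethanol in C57BL/6J and 25 and 31 for conditioning in C57BL/6J and DBA/2J. With an estimated correlation the lists called were 0 for strain, 2 for ethanol in each strain, 1 for conditioning in C57BL/6J and 0 in DBA/2J. At the preset correlation the choroid plexus covariate gave 14 for conditioning in DBA/2J, of which 6 were among the 9 called without it, and the smallest adjusted p with an estimated correlation was then 0.2.

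Leaving out 1 library gave 9827 to 10136 genes for strain, 39 to 45 for sex, 10 (without B6_F_FC_SAL_319) to 20 for ethanol in C57BL/6J and 42 to 84 for ethanol in DBA/2J. Ethanol by strain gave 0 to 5 (highest without DBA_F_noFC_SAL_317), with 34 of 63 fits beyond 1.5 times. Conditioning gave 0 to 4 in C57BL/6J (highest without B6_M_FC_EtOH_322) and 0 to 1 in DBA/2J (1 without DBA_M_noFC_EtOH_316). Ethanol by conditioning gave 0 to 2 in C57BL/6J (2 without B6_M_FC_EtOH_310), and conditioning by sex 0 to 297 (297 without DBA_M_noFC_EtOH_312). Leaving out 1 title number gave usage counts of 2270 to 2445 for strain, 33 (without the number of B6_M_FC_EtOH_310; 46 without that of B6_F_FC_SAL_319) to 111 for ethanol in C57BL/6J, 84 (without that of DBA_F_FC_EtOH_321) to 144 in DBA/2J, 32 (without that of B6_M_FC_EtOH_322; 35 without that of B6_M_FC_SAL_318) to 65 for conditioning in C57BL/6J and 41 to 64 in DBA/2J. Of the named genes under alternatives, 3710 values kept their side of the threshold, 128 lost and 38 gained a call and 1 was reversed. A change of sign was counted as reversed only where either fit called the gene, so the 3710 can include uncalled values of changed sign. In simulated data ethanol by strain recovered 34.3% of changes of 0.25, so smaller differences are often missed.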

Other observations

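The test of opposite signs was chosen after the result was seen. In C57BL/6J, 26 of the 32 immediate early genes had opposite signs for ethanol and for conditioning; Arc went from 190 ± 35.1 to 239 ± 54.6 CPM (SD, n = 16 and 15) with conditioning, and from 247 ± 45.8 to 182 ± 34.3 CPM (n = 15 and 16) with ethanol. In 10000 random lists of like expression the median was 16, and the share with as many was 2e-04. That comparison decides nothing, since 26 genes lower with ethanol and 30 higher with conditioning already fix at least 24 opposite signs, with 24.8 expected. Gene by gene no relation was found (Fisher's exact p = 0.34 for the signs; Pearson r -0.03 and Spearman rho -0.08 over the list), so the opposition follows from the shift of each list as a whole. In DBA/2J 20 of 32 had opposite signs, and over all genes in C57BL/6J 50.3%.

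Xist and Ddx3y fitted the labelled sex in all 63 libraries. Xist was at 0.124 to 7.9 CPM (median 1.13) in the 31 males, at most 0.877% of the female mean, and above 1 CPM in 17 of them. Ddx3y was at 0 to 1.8 CPM (median 0.193) in the 32 females, at most 2.65% of the male mean.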
